A study of Mus musculus with 12 samples.

How the data were processed

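RNA was sequenced from livers of C57BL/6 mice aged 15 months, per the labels, in 4 groups of 3 libraries: tumours and non-tumour liver of Atg7 knockouts (Atg7KO) and of Atg7 and Hmgb1 double knockouts (DKO). The deposited values are raw counts, whole numbers of reads per RefSeq gene, in a table of 24421 genes by 12 libraries that also gives gene lengths in bases and mm10 coordinates. Per the submitters' processing notes, reads were handled with bcl2fastq, STAR 2.5.3a, featureCounts of Subread 1.5.3 and edgeR 3.20.8 on mm10, from total RNA. The strand setting, annotation release and library kit were not given in the sources used here. Reads of genes that overlap on opposite strands can therefore be mixed, as for Acss2, Lpp, Xist, Peg3 and Cela2a, and reads of close paralogues can be shared or lost, as for Bglap3, Mthfsl and the Cyp3a, Cyp2c and Sult2a families. Of the names, 27 had been turned into date numbers and all 27 were restored from the RefSeq accession.

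Library totals ran from 18292190 reads in DKO non-tumour replicate 2 to 32354958 in DKO tumour replicate 1. Intervals from these counts would cover counting error only and not the spread between libraries, for which the common biological coefficient of variation was 0.3647. Counting error is large for genes with few reads, such as Bglap3 and Xist in DKO and the Y genes in Atg7KO. No library looked like a copy of another: the highest Spearman correlation between libraries was 0.9858, of DKO non-tumour replicate 3 with DKO tumour replicate 3. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples. Tumour and non-tumour libraries share only a number in the labels, so they were not treated as pairs, and a replicate block was run as an alternative. The labels give no sex and no batch.

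Genes with low counts were left out with filterByExpr (minimum count 10, minimum total 15), which left 14443 genes; 4509 genes had no read in any library. Counts were scaled with TMM factors and tested with the edgeR 4.0.16 quasi-likelihood F test, robust and with legacy deviances, in 1 fit of all 12 libraries with a term per group, in R 4.3.3. The comparisons were tumour minus non-tumour in each genotype, DKO minus Atg7KO in each tissue, and the interaction. Tests were two-sided, and p was adjusted by Benjamini-Hochberg within each comparison, with calls at an adjusted p under 0.05. CPM values are TMM-scaled. An exact permutation test of 3 against 3 libraries cannot go below 0.1, so none was run for single values. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run beside edgeR. DESeq2 was run and its calls counted on all genes with any read, a set larger than the 14443. Its filter left 4763 to 9306 genes of that set without an adjusted p. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

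The gene lists, 34 in number, were written from general knowledge of liver biology before the data were examined, together with the comparisons, tests, other settings to try and the rule for naming genes. They covered liver zones, metabolism, stress pathways, cell cycle, oncofetal genes and markers of other cell types. In all 31 were tested with camera (preset correlation 0.01) on voom values, beside camera with an estimated correlation and the fry test, with p adjusted over the 31 lists in each comparison. Camera called 19, 16, 10, 10 and 8 lists in the 5 comparisons in the order above. With an estimated correlation it called 0 in each, with lowest adjusted p of 0.0908, 0.539, 0.761, 0.745 and 0.564, and fry called 1, 0, 0, 0 and 0. No called list had a median and a test that differed in sign. Pancreatic acinar genes were not tested because 2 of 12 passed the filter, genes of the mitochondrial genome because the table holds 0 of 15, and sex chromosome genes served as a check. Missing from the table under the names listed were Ighm, Igkc, Ly6g, Epb42, Ccn1, Ccn2 and 6 ATP synthase names, some of which it holds under older names. List scores are means over members of log2 CPM (prior count 2), centred on the 12 libraries.

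Named were Atg7 and Hmgb1 everywhere and, per comparison, the 5 largest rises and falls among edgeR calls with at least 5 CPM in the higher group, no overlap between the libraries and a symbol that is not a predicted model. Also named were the 3 called members with the largest change of the 6 lists with the lowest camera p, the best called member of other lists, and the member with the highest CPM of a list without calls. For the interaction the rule took the lowest adjusted p instead. Because edgeR called few genes, 2 rules were added after the data were seen: the same choice among DESeq2 calls, and up to 3 members with the lowest p past 0.05 adjusted over the list alone. Coq10b and Mthfsl in non-tumour liver, and Nqo1, Igf2, H19, Sqstm1 and Gpc3, fall outside these rules and were named after their values were seen.

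Alternatives were RLE factors, DESeq2, no filter, a filter at 1 CPM in 3 libraries, robust estimation off, the replicate block, only the 2 groups compared, and each library left out in turn. Added after the data were seen were an offset for gene length, an offset for length and GC content, edgeR without legacy deviances, voom with quality weights, and the length offset without DKO non-tumour replicate 3. The length offset is, per library, a loess curve (span 0.3) of the deviation in log2 CPM on log2 gene length.

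The pipeline was tested on simulated counts with the libraries' depths and spread, no length trend and 200 changed genes. For folds of 2, 4 and 8 edgeR recovered 19.4%, 73.1% and 87.9% between tumour and non-tumour in Atg7KO (14332 genes run), and 8.96%, 65.7% and 77.3% in DKO (14338 genes). Between the genotypes it recovered 8.96%, 71.6% and 83.3% in non-tumour liver (14334 genes) and 7.46%, 62.7% and 86.4% in tumours (14336 genes), and for the interaction 4.48%, 49.3% and 63.6% (14317 genes). Calls of unchanged genes numbered 5, 4, 1, 1 and 5 for edgeR. For DESeq2 they numbered 39 of 190, 37 of 173, 44 of 183, 29 of 155 and 35 of 140 calls, so its counts are given beside those of edgeR and not in their place. Camera recovered a simulated list in all 5 comparisons and called 1 unchanged list, in the interaction. This says nothing of calls lost with an estimated correlation. Most changes of 2-fold would thus be missed in single genes.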

Results

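The labels name livers of 15-month-old mice lacking Atg7, which is needed to form autophagosomes, or lacking Atg7 together with the chromatin and danger-signal protein Hmgb1. Tumours and non-tumour liver were sequenced in each genotype, called Atg7KO and DKO from here on, with 3 libraries in each of the 4 groups. Values per group are means of TMM-scaled CPM (reads of a gene scaled to library size) with the SD of n = 3 libraries, and differences are log2 fold changes with their SE from edgeR. The question the labels set is how tumours differ from the liver around them, and whether the loss of Hmgb1 changes either tissue.

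Reads of both deleted genes were present in every library. Atg7 (NM_001253718, mm10 chromosome 6, 114643097 to 114860614) stood at 10.1 ± 2.70 CPM in Atg7KO non-tumour liver, 5.56 ± 2.61 in Atg7KO tumours, 13 ± 4.13 in DKO non-tumour liver and 6.96 ± 3.40 in DKO tumours, from 88 to 401 reads per library. Hmgb1 (NM_010439, mm10 chromosome 5, 149047227 to 149053037) stood at 118 ± 12.3, 115 ± 20.4, 101 ± 17.4 and 79.0 ± 16.3 CPM in the same order. The counts cover whole genes, so they include exons that a deletion leaves in place and transcripts of other cells, and no wild-type liver was sequenced. Sqstm1, which encodes the autophagy cargo receptor p62 and is itself an NRF2 target, stood at 852 ± 173, 1350 ± 594, 747 ± 77.8 and 891 ± 145 CPM.

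**Figure D1:**
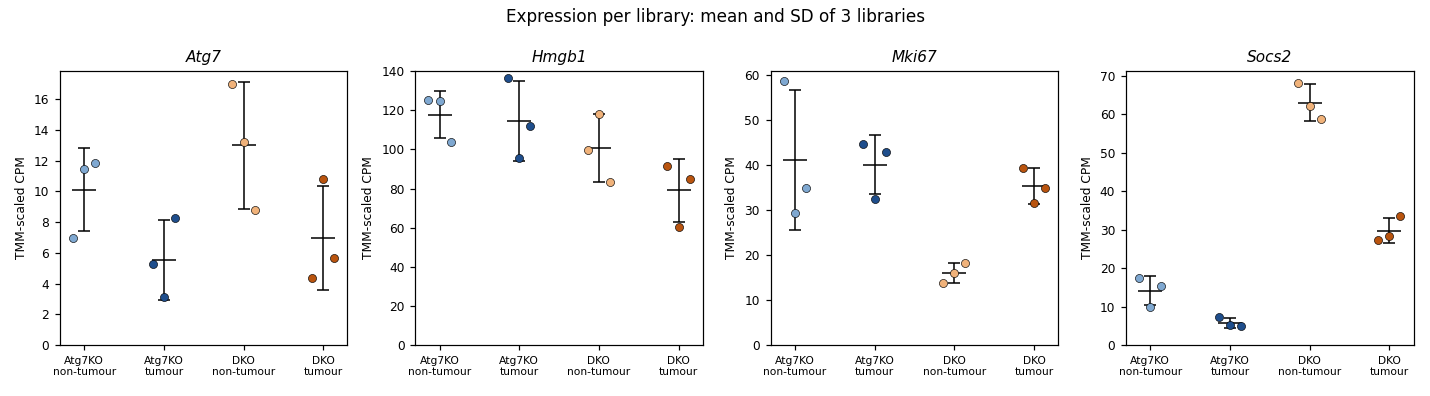
TMM-scaled CPM on linear axes for Atg7, Hmgb1, the proliferation marker Mki67 and the growth hormone feedback gene Socs2; points are the 3 libraries of each group, with the group mean and SD. Socs2 stood at 14.2 CPM in Atg7KO and 63.0 CPM in DKO non-tumour liver, and Mki67 at 41.1 and 16.1 CPM.

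The genotypes also differed in sex chromosome transcripts, which no label mentions. Ddx3y, Eif2s3y, Kdm5d and Uty, carried on the Y chromosome, summed to between 0 and 2 reads in each Atg7KO library and to between 1898 and 4639 reads in each DKO library. Xist, the RNA that silences one X chromosome in females, had 1130 to 12216 reads in each Atg7KO library and 0 to 2 in each DKO library. Every difference between the genotypes given here therefore runs together with this difference.

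**Figure D2:**
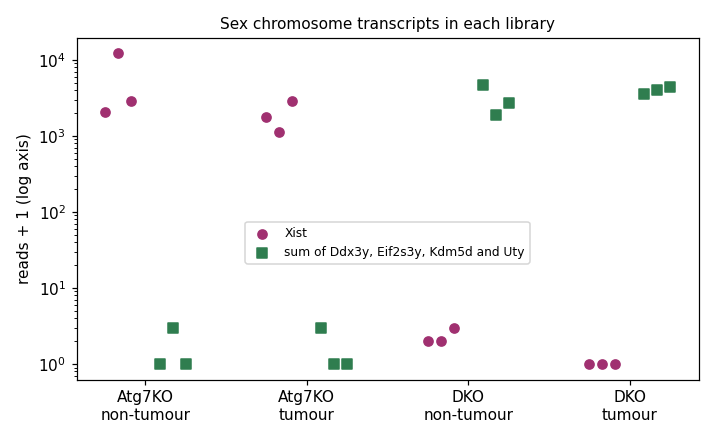
Reads plus 1 on a log axis for each of the 12 libraries, with Xist as circles and the sum of 4 Y chromosome genes as squares. Xist reached at least 1130 reads in all 6 Atg7KO libraries, and the Y genes at least 1898 reads in all 6 DKO libraries.

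In Atg7KO tumours the genes of pericentral hepatocytes, the cells around the central vein that depend on Wnt signalling, fell. Cyp2e1 (NM_021282, mm10 chromosome 7, 140763832 to 140774977), which oxidises ethanol and paracetamol, went from 3077 ± 2920 CPM to 145 ± 94.6 CPM, a log2 fold change of -4.41 with an SE of 0.92. The Wnt feedback gene Axin2 went from 12.4 ± 1.54 to 2.82 ± 0.975 CPM and the zonal transcription factor Tbx3 from 33.2 ± 11.3 to 4.01 ± 1.81 CPM. For each of these 3 genes all 3 tumour libraries lay below all 3 non-tumour libraries. All 22 tested members of the list were below 0, with a median of -2.16 (camera adjusted p = 2.14e-11, and 0.445 with an estimated correlation). Of the list 16 members passed adjusted over the list alone, against 0 adjusted over all genes, and this count was 8 without Atg7KO non-tumour replicate 2 and 8 without Atg7KO tumour replicate 3. Rspo3, the endothelial Wnt amplifier that maintains this zone, went from 7.22 ± 1.75 to 1.93 ± 0.727 CPM, within an endothelial list that fell by a median of 0.27 (camera adjusted p = 0.00971, and 0.445 with an estimated correlation). Rspo3 was the 1 endothelial member of 18 that passed adjusted over the list alone, against 0 over all genes, with 2 without Atg7KO non-tumour replicate 1 or tumour replicate 2.

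Targets of p53 rose in the same tumours, among them the cell cycle inhibitor Cdkn1a (50.7 ± 24.2 to 122 ± 35.0 CPM), the death receptor Tnfrsf10b (6.35 ± 2.64 to 20.1 ± 1.29 CPM) and the mitochondrial pore protein Bax (27.2 ± 8.69 to 53.1 ± 12.2 CPM). In all 3 tumour libraries each of these 3 genes was above all 3 non-tumour libraries. The 20 members had a median of 0.95 with 19 above 0 (camera adjusted p = 1.55e-09, and 0.0908 with an estimated correlation), and fry, which asks whether the list moves one way, gave an adjusted p of 0.00924. Here 9 members passed adjusted over the list alone, against 0 over all genes. The count was 0 without Atg7KO non-tumour replicate 2 and 5 without Atg7KO tumour replicate 2, where the median was 0.52. Targets of NRF2, the antioxidant factor that p62 releases from KEAP1, rose with 28 of 30 above 0 and a median of 0.71 (camera adjusted p = 1.55e-09, and 0.445 with an estimated correlation). Nqo1 stood at 175 ± 84.6 CPM in non-tumour liver and 397 ± 15.1 CPM in tumours, and the glutathione transferase Gstm1 at 9046 ± 4180 and 15430 ± 471 CPM. No NRF2 target passed over all genes or adjusted over the list alone, but 17 did without Atg7KO non-tumour replicate 1, 3 without DKO non-tumour replicate 3 and 1 without DKO tumour replicates 1 or 3.

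Metabolic enzymes made the next group that fell. For cytochrome P450 and related drug-handling genes the median was -0.90, with 26 of 31 below 0 (camera adjusted p = 4.48e-05, and 0.445 with an estimated correlation). Cyp2b9 of this list went from 213 ± 243 to 9.09 ± 8.44 CPM. Genes that female livers express more fell by a median of 2.58, with 14 of 15 below 0 (camera adjusted p = 1.13e-06, and 0.359 with an estimated correlation). They include Cyp2b9. Without Atg7KO non-tumour replicate 2 their median was -1.21. Lipogenic genes fell by a median of 1.17, or 0.53 without Atg7KO non-tumour replicate 2, with 18 of 20 below 0 (camera adjusted p = 9.91e-06, and 0.518 with an estimated correlation). In that list the phosphatidate phosphatase Lpin1 went from 212 ± 85.5 to 83.6 ± 18.7 CPM and the acetyl-CoA synthetase Acss2, whose locus overlaps the antisense transcript Acss2os, from 256 ± 116 to 124 ± 6.93 CPM. In these lists 11 P450, 8 female-biased and 5 lipogenic genes passed adjusted over the list alone, against 0 of each over all genes. The P450 count was 0 without Atg7KO tumour replicate 1 or 3, 1 without Atg7KO non-tumour replicate 2 or tumour replicate 2, and 7 without DKO non-tumour replicate 2. The female-biased count was 2 without Atg7KO tumour replicate 1, 3 without non-tumour replicate 2 and 4 without tumour replicate 3. The lipogenic count was 0 without any 1 of Atg7KO tumour replicates 1, 2 and 3, Atg7KO non-tumour replicate 2, the 3 DKO non-tumour libraries or DKO tumour replicate 3. It was 10 or 11 without Atg7KO non-tumour replicate 1, Atg7KO non-tumour replicate 3 or DKO tumour replicate 1.

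Markers of bile duct cells and of stellate cells fell in Atg7KO tumours. The duct list had a median of -1.58 (camera adjusted p = 0.000139, and 0.518 with an estimated correlation), and its surface protein Epcam went from 21.3 ± 10.6 to 3.44 ± 3.67 CPM. The stellate list had a median of -0.79 (camera adjusted p = 0.00196, and 0.635 with an estimated correlation). Its receptor gene Pdgfra had the lowest adjusted p over all genes in this comparison, 0.0845, at 27.5 ± 11.6 and 6.17 ± 1.16 CPM, a log2 fold change of -2.15 with an SE of 0.32. The matrix gene Dcn went from 328 ± 62.0 to 130 ± 43.2 CPM, while the collagen cross-linker Loxl2 went the other way, from 11.7 ± 5.34 to 41.8 ± 22.2 CPM. Adjusted over the list alone, 4 duct markers were lower and 1 higher, and 8 stellate markers were lower and 2 higher, against 0 over all genes. The lower duct count was 0 without Atg7KO non-tumour replicate 1 or tumour replicates 1 or 3, 7 without non-tumour replicate 2 and 12 without tumour replicate 2. The higher duct marker was lost without any 1 of Atg7KO non-tumour replicates 1, 2 and 3, Atg7KO tumour replicates 1 and 3, and the 3 DKO non-tumour libraries. The lower stellate count was 4 without Atg7KO non-tumour replicate 1, 5 without tumour replicate 1 and 3 without tumour replicate 3. The higher stellate count was 1 without any 1 of the 3 Atg7KO tumour libraries, Atg7KO non-tumour replicates 2 and 3, DKO non-tumour replicate 1, and DKO tumour replicates 2 and 3. The stellate list call was lost without Atg7KO non-tumour replicate 1 (camera adjusted p = 0.197), where the median was -0.32.

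Oncofetal genes, a list of genes often raised in liver cancer, rose with a median of 1.59 and 16 of 19 above 0 (camera adjusted p = 0.00271, and 0.518 with an estimated correlation). Without Atg7KO tumour replicate 1 that median was 0.72. Igf2bp3, an RNA-binding protein of fetal liver, went from 1.69 ± 1.96 to 13 ± 6.83 CPM and the Golgi protein gene Golm1 from 38.7 ± 18.1 to 97.1 ± 22.3 CPM. Adjusted over the list alone, 4 were higher and 1 lower, against 0 over all genes. The higher count was 2 without Atg7KO non-tumour replicate 1 or DKO tumour replicate 2, 1 without Atg7KO non-tumour replicate 2, 7 without Atg7KO tumour replicate 2, and 0 without Atg7KO tumour replicate 1 or non-tumour replicate 3. The lower gene was lost without Atg7KO non-tumour replicates 1 or 3, Atg7KO tumour replicates 1 or 3, or DKO tumour replicate 2, and the list call without Atg7KO non-tumour replicate 2 (camera adjusted p = 0.0697). The asparagine synthetase Asns, a target of the amino acid stress factor ATF4, went from 2.78 ± 2.06 to 25.8 ± 20.3 CPM. Adjusted over the list alone, 2 of 21 ER stress genes were higher and 1 lower, against 0 over all genes, and the list itself was not called (camera adjusted p = 0.215). The higher ER stress count was 0 without Atg7KO non-tumour replicates 1 or 2 or Atg7KO tumour replicates 2 or 3, 1 without Atg7KO tumour replicate 1, Atg7KO non-tumour replicate 3 or DKO non-tumour replicate 2, and 4 without DKO tumour replicate 1. The lower ER stress gene was lost without any 1 of the 6 Atg7KO libraries and DKO non-tumour replicates 1 and 2. Cxcl12, the chemokine with which HMGB1 forms a complex, went from 394 ± 46.9 to 151 ± 22.7 CPM and was the 1 of 12 HMGB1 partner genes to pass adjusted over the list alone, against 0 over all genes, with 2 without Atg7KO non-tumour replicate 2. The autophagy gene Atg12 went from 55.2 ± 9.62 to 124 ± 30.5 CPM and passed alone in its list, though not without Atg7KO non-tumour replicates 2 or 3, nor over all genes.

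Cell cycle lists rose in Atg7KO tumours. S phase genes rose by a median of 0.40 with 24 of 25 above 0 (camera adjusted p = 8.3e-06, and 0.503 with an estimated correlation), and G2/M genes by 0.43 with 24 of 25 above 0 (camera adjusted p = 4.35e-05, and 0.635 with an estimated correlation). The G2/M median was 0.16 without Atg7KO non-tumour replicate 2 and 0.97 without replicate 1. Mki67 itself stood at 41.1 ± 15.6 and 40.1 ± 6.58 CPM. Without Atg7KO non-tumour replicate 1, 17 G2/M and 4 S phase genes passed adjusted over the list alone, and without DKO tumour replicate 3 there was 1 S phase gene. YAP targets are among the lists with 0, but 7 passed without DKO tumour replicate 1 and 1 without Atg7KO tumour replicate 2. Oxidative phosphorylation genes were higher by a median of 0.21 (camera adjusted p = 0.00167, and 0.635 with an estimated correlation). That call was lost without Atg7KO non-tumour replicate 3 (0.201, with a median of 0.10), and with an offset for gene length the direction reversed (0.638, with a median of -0.04). Autophagy genes rose by 0.15 (camera adjusted p = 0.0143, and 0.359 with an estimated correlation) and interferon response genes by 0.33 (0.0097, and 0.635). Fatty acid oxidation genes fell by 0.46 (0.00723, and 0.635), YAP targets by 0.46 (0.00971, and 0.635), B and plasma cell markers by 0.70 (0.0119, and 0.635) and cholesterol synthesis genes by 0.36 (0.0143, and 0.635). Each of these 6 calls was lost on leaving out a library. Autophagy was lost without Atg7KO non-tumour replicate 1 (0.0726), interferon without Atg7KO tumour replicate 1 or 3 or non-tumour replicate 2 (up to 0.247) and fatty acid oxidation without Atg7KO non-tumour replicate 2 or tumour replicate 2 (up to 0.901). YAP was lost without Atg7KO non-tumour replicate 1 (0.074), B cells without Atg7KO tumour replicate 2 or non-tumour replicate 3 (up to 0.368) and cholesterol without Atg7KO non-tumour replicate 2 or tumour replicate 2 (up to 0.578). Without Atg7KO non-tumour replicate 2 the fatty acid oxidation median turned to 0.03 and the cholesterol median was -0.10. The interferon median was 0.08 without Atg7KO tumour replicate 1, and the B cell median -0.33 without Atg7KO tumour replicate 2 and -0.16 without non-tumour replicate 3.

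No single gene passed in edgeR between Atg7KO tumours and non-tumour liver, where 2423 of 14443 genes (16.8%) had an unadjusted p under 0.05, DESeq2 called 261 higher and 350 lower, and limma voom with quality weights called 105 higher and 227 lower. In 3392 genes (23.5%) the 3 libraries of one group lay beyond the 3 of the other, against 10% by chance. Among the DESeq2 calls were Bglap3, a gene of the osteocalcin family whose reads 2 paralogues can share, at 0.220 ± 0.129 and 11.4 ± 7.97 CPM, and the neuropeptide-processing enzyme gene Cpe at 7.54 and 125 ± 77.4 CPM. Lists that camera did not call were secreted plasma proteins (adjusted p = 0.0756, and 0.0147 with the length offset), neutrophil (0.0791, and 0.0342), bile acid (0.0793), inflammatory cytokine (0.103), acute phase (0.189). The same held for T and NK cell (0.215), male-biased (0.215), erythroid (0.37), periportal (0.45), macrophage (0.564) and HMGB1 partner genes (0.751).

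**Figure D3:**
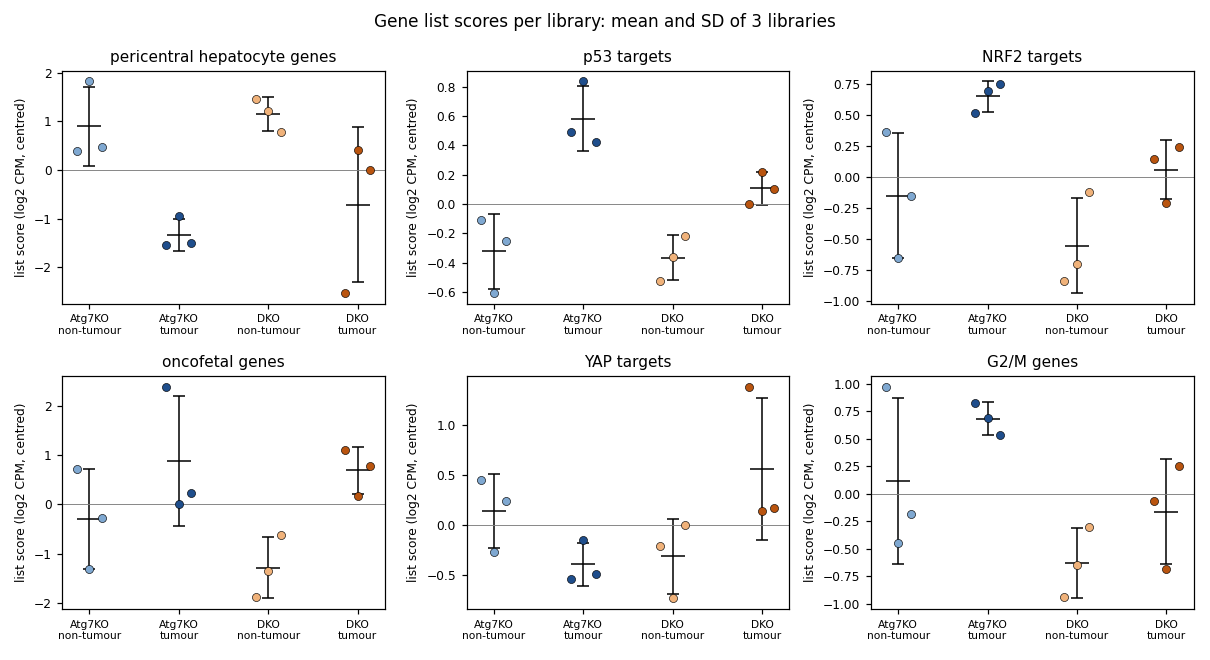
List scores, the mean over list members of log2 CPM centred on all 12 libraries, for 6 lists in the 4 groups; points are libraries and bars the mean ± SD of 3. Pericentral scores ran from -1.55 to -0.96 in Atg7KO tumours and from 0.39 to 1.82 in the non-tumour liver beside them.

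In DKO tumours nuclear genes of oxidative phosphorylation, the respiratory chain of mitochondria, fell as a block. The complex I genes Ndufa5 (74.3 ± 21.3 to 35.3 ± 3.12 CPM) and Ndufb6 (65.2 ± 14.5 to 33.9 ± 8.03 CPM) and the complex III gene Uqcrq (349 ± 145 to 123 ± 34.9 CPM) were lower in all 3 tumour libraries than in any of 3 non-tumour libraries. All 47 members lay below 0, with a median of -0.74 (camera adjusted p = 1.2e-20, and 0.539 with an estimated correlation). In it 38 passed adjusted over the list alone, against 0 over all genes, and the count was 22 without DKO non-tumour replicate 1, 0 without DKO non-tumour replicate 2 and 20 without DKO tumour replicate 2. In this comparison log2 fold changes followed gene length across genes with a Spearman rho of 0.495, and the list is short, with a median length of 903 bp against 2862 bp for all genes. With an offset for gene length 0 members passed adjusted over the list alone, the score difference went from -0.71 with an SE of 0.18 to -0.23 with an SE of 0.13, and the camera adjusted p was 1.28e-05. Fatty acid oxidation genes fell by a median of 0.77 with 26 of 30 below 0 (camera adjusted p = 9.77e-06, and 0.539 with an estimated correlation). Of them 0 passed over all genes or adjusted over the list alone, though 12 did without Atg7KO non-tumour replicate 2 and 3 without DKO tumour replicate 3.

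Pericentral genes fell in DKO tumours as well, with all 22 below 0 and a median of -1.42 (camera adjusted p = 1.47e-08, and 0.539 with an estimated correlation). Cyp2e1 stood at 5615 ± 2750 CPM in non-tumour liver and 1289 ± 928 CPM in tumours, and 0 members passed adjusted over the list alone or over all genes. The 3 DKO tumours were spread widely in this list, with scores of -2.54, 0.40 and 0.00, the lowest in replicate 1. Periportal genes, which carry out urea and amino acid metabolism, fell by a median of 0.81 (camera adjusted p = 0.00886, and 0.539 with an estimated correlation), although the glycine decarboxylase Gldc went up from 97.3 ± 36.3 to 225 ± 39.5 CPM and was the 1 member to pass adjusted over the list alone, against 0 over all genes. Gldc was lost without any 1 of Atg7KO non-tumour replicates 1 and 3, Atg7KO tumour replicate 2, DKO non-tumour replicates 1 and 2, and DKO tumour replicates 1 and 3, and 2 members were higher without Atg7KO non-tumour replicate 2 or DKO non-tumour replicate 3. Lower periportal genes numbered 2 without DKO non-tumour replicate 3 and 1 without Atg7KO non-tumour replicate 2 or DKO tumour replicate 3. Secreted plasma proteins fell by 0.76 (camera adjusted p = 0.00028, and 0.539 with an estimated correlation), drug-handling genes by 0.60 (0.00338, and 0.539) and bile acid genes by 0.86 (0.00695, and 0.539). Lipogenic genes fell by 0.60 (0.00588, and 0.731), a call lost without DKO tumour replicate 1 (0.332). Acute phase genes fell by 0.83 (0.00683, and 0.731), lost without DKO tumour replicate 1 or non-tumour replicate 2 (up to 0.413), and without the latter the median turned to 0.07. Female-biased genes fell by 1.25 (0.0249, and 0.56), or 0.34 without DKO non-tumour replicate 2, and the call was lost without DKO tumour replicate 1 (0.196). Plasma and B cell markers fell by 1.03 (0.0238, and 0.731), lost without DKO non-tumour replicate 1 or tumour replicate 3 (up to 0.218). In these lists 0 passed adjusted over the list alone, but without DKO non-tumour replicate 3 there were 3 secreted protein and 4 plasma and B cell genes. Lower bile acid genes numbered 3 without Atg7KO non-tumour replicate 2 or DKO tumour replicate 2 and 1 without DKO tumour replicate 3, with 1 higher without DKO tumour replicate 2, where 2 female-biased genes passed too.

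Oncofetal genes rose in DKO tumours, with a median of 1.94 and 18 of 19 above 0 (camera adjusted p = 0.000181, and 0.539 with an estimated correlation). Igf2bp3 went from 0.507 ± 0.150 to 8.26 ± 0.485 CPM, a log2 fold change of 4.00 with an SE of 0.81. Afp, the fetal albumin used as a liver cancer marker, went from 19 ± 9.67 to 937 ± 1200 CPM, of which replicate 1 alone had 2320 CPM. Of its members 8 passed adjusted over the list alone, against 0 over all genes, and this was 2 without DKO non-tumour replicate 1 or 2 and 3 without DKO tumour replicate 1. Targets of YAP, the transcriptional co-activator restrained by Hippo signalling, rose with all 18 above 0 and a median of 0.70, or 0.30 without DKO tumour replicate 1 (camera adjusted p = 0.000181, and 0.539 with an estimated correlation). The YAP partner Tead1 went from 18 ± 6.12 to 51.7 ± 22.2 CPM, a log2 fold change of 1.52, or 0.91 with the length offset, and the phosphatase Ptpn14 from 19.2 ± 12.4 to 89.7 ± 33.1 CPM. Within the list 5 YAP targets passed adjusted over the list alone, against 0 over all genes, and 0 did without DKO non-tumour replicates 1 or 2 or tumour replicate 1. The YAP scores of the DKO tumours were 1.39 in replicate 1 and 0.15 and 0.17 in the others.

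NRF2 targets rose in DKO tumours with 26 of 30 above 0 and a median of 0.65 (camera adjusted p = 3.03e-05, and 0.539 with an estimated correlation), led by the efflux pump Abcc4 at 89.7 ± 52.0 and 318 ± 123 CPM. Abcc4 alone passed adjusted over the list alone, against 0 over all genes. The count was 0 without DKO non-tumour replicates 1 or 2 or tumour replicate 1, 3 without DKO non-tumour replicate 3 and 2 without DKO tumour replicate 3. For p53 targets the median was 0.44 (camera adjusted p = 0.0465, and 0.539 with an estimated correlation), a call lost without DKO non-tumour replicates 1 or 3 or tumour replicates 2 or 3 (up to 0.132). Tnfrsf10b went from 4.90 ± 2.30 to 13.5 ± 2.82 CPM and the p53 ubiquitin ligase Mdm2 from 39.9 ± 6.21 to 62.3 ± 11.9 CPM. In this list 4 p53 targets passed adjusted over the list alone, against 0 over all genes, with 0 without DKO non-tumour replicates 1 or 2 and 2 without tumour replicate 1. Another 2 were lower without DKO non-tumour replicate 3. G2/M genes rose by a median of 0.53 (camera adjusted p = 0.00397, and 0.772 with an estimated correlation), a call lost without DKO tumour replicate 3 (0.126), where the median was 0.26. Mki67 went from 16.1 ± 2.25 to 35.3 ± 3.99 CPM, with a log2 fold change of 1.14, or 0.51 with the length offset. It was the 1 G2/M gene to pass adjusted over the list alone, against 0 over all genes, and did not without DKO non-tumour replicates 1 or 2 or tumour replicates 1 or 3. Asns went from 4.76 ± 1.09 to 57.6 ± 42.1 CPM and Cxcl12 from 338 ± 111 to 162 ± 21.9 CPM, and each passed adjusted over the list alone, against 0 over all genes, in a list that camera did not call. Asns did not without DKO non-tumour replicates 2 or 3, and 2 ER stress genes passed without DKO tumour replicate 2. Cxcl12 did not without DKO non-tumour replicate 1 or DKO tumour replicates 1 or 2.

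No single gene passed in edgeR between DKO tumours and non-tumour liver, with a lowest adjusted p of 0.117. Unadjusted p was under 0.05 for 3251 genes (22.5%), DESeq2 called 600 higher and 502 lower, and limma voom with quality weights called 0 and 0. Without DKO non-tumour replicate 3, edgeR called 297 higher and 300 lower, and with the length offset added 0. The 2 groups did not overlap in 3886 genes (26.9%), against 10% by chance. DESeq2 called Fabp1, the fatty acid binding protein of hepatocytes, at 2892 ± 1750 and 585 ± 455 CPM, the antimicrobial peptide gene Leap2 at 17.2 ± 7.10 and 3.36 ± 2.18 CPM, and the guidance factor gene Sema3e at 0.485 and 14.9 ± 17.5 CPM. Lists not called by camera were cholesterol synthesis (adjusted p = 0.0692, and 0.0136 with the length offset), T and NK cell (0.0725), interferon (0.0924), stellate (0.0993), macrophage (0.2), autophagy (0.205). The same held for neutrophil (0.205), erythroid (0.219), S phase (0.347), inflammatory cytokine (0.54), male-biased (0.572), HMGB1 partner, ER stress and endothelial (0.903 each) and duct genes (0.998).

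Across the 14443 genes the tumour effects of the genotypes correlated with a Pearson r of 0.3263 and a Spearman rho of 0.1856, and 52.93% of genes had the same sign, though genes are not independent replicates. At an unadjusted p under 0.05 in both, 201 genes were higher in both genotypes against 142 expected by chance, 167 lower against 129, and 174 opposite against 274.

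In non-tumour liver the gene that separated the genotypes most firmly outside the sex chromosomes was Socs2 (NM_007706, mm10 chromosome 10, 95411490 to 95416857), which feeds back on growth hormone signalling. It rose from 14.2 ± 3.81 CPM in Atg7KO to 63.0 ± 4.70 CPM in DKO, a log2 fold change of 2.15 with an SE of 0.23 and an edgeR adjusted p of 0.00282, with all 3 DKO libraries above all 3 Atg7KO libraries. Coq10b (NM_001039710, mm10 chromosome 1, 55052770 to 55072702), which helps coenzyme Q work in the respiratory chain, rose from 21.6 ± 3.40 to 66.3 ± 4.49 CPM (log2 fold change 1.62, SE 0.19, adjusted p = 0.00602), though it was not called without Atg7KO non-tumour replicate 3 (0.0594). Mthfsl (NM_001128601, mm10 chromosome 9, 88688605 to 88719798), a gene of folate metabolism with paralogues that can share reads, rose from 17.6 ± 0.561 to 40.4 ± 7.87 CPM (log2 fold change 1.19, SE 0.17, adjusted p = 0.0276). The Mthfsl call was lost without Atg7KO non-tumour replicate 1 (0.233), 2 (0.153) or 3 (0.2) or DKO non-tumour replicate 1 (0.162) or 2 (0.154). It was also lost without Atg7KO tumour replicate 1 (0.0532), 2 (0.0586) or 3 (0.0746) or DKO tumour replicate 2 (0.0563) or 3 (0.0696). With the length offset its log2 fold change was 0.69 (0.372), with GC content added 0.62 (0.441), and with only the 2 groups fitted it was not called either (0.144). The other edgeR calls were Ddx3y (60.1 ± 12.6 CPM in DKO, adjusted p = 4.39e-06), Eif2s3y (48.0 ± 2.63 CPM, 4.39e-06), Kdm5d (12.7 ± 1.06 CPM, 0.00011) and Uty (11.7 ± 6.15 CPM, 0.00282), each at 0 to 0.0265 CPM in Atg7KO, and Xist, at 214 ± 235 CPM in Atg7KO and 0.059 ± 0.0144 CPM in DKO (0.00663). Xist, whose locus overlaps the antisense gene Tsix, was not called without DKO non-tumour replicate 1 (0.109), 2 (0.0922) or 3 (0.0728), nor without the low-count filter (0.066). In total edgeR called 7 genes higher and 1 lower in DKO, 2175 genes (15.1%) had an unadjusted p under 0.05, DESeq2 called 87 higher and 102 lower, limma voom with quality weights called 338 higher and 223 lower, and 3433 genes (23.8%) did not overlap, against 10% by chance.

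Of the 2 cell cycle lists, G2/M genes were lower in DKO non-tumour liver and S phase genes were not called (camera adjusted p = 0.684). Mki67 stood at 41.1 ± 15.6 CPM in Atg7KO and 16.1 ± 2.25 CPM in DKO, a log2 fold change of -1.35 with an SE of 0.26 (edgeR adjusted p = 0.17), with no overlap between the 3 and 3 libraries. The spindle motor gene Cenpe stood at 7.82 ± 3.59 and 3.36 ± 0.858 CPM and the spindle assembly gene Tpx2 at 13.8 ± 9.24 and 5.09 ± 2.19 CPM. All 25 G2/M genes were below 0, with a median of -0.78, or -0.32 without Atg7KO non-tumour replicate 1 (camera adjusted p = 5.56e-07, and 0.944 with an estimated correlation). Of the list 5 passed adjusted over the list alone, against 0 over all genes. That count was 17 without Atg7KO non-tumour replicate 2 and 1 without any 1 of Atg7KO non-tumour replicate 1, Atg7KO tumour replicates 1 and 3, DKO non-tumour replicates 1 and 2, and DKO tumour replicate 3. Log2 fold changes followed gene length here with a rho of -0.474 across genes, and with the length offset Mki67 stood at -0.85 and 0 G2/M genes passed adjusted over the list alone. Oxidative phosphorylation genes rose in DKO, with 45 of 47 above 0 and a median of 0.48 (camera adjusted p = 2.34e-12, 0.944 with an estimated correlation, and 0.669 with the length offset, where the median was 0.01). The cytochrome oxidase subunit Cox7a2 stood at 84.6 ± 9.84 and 169 ± 43.3 CPM, with a log2 fold change of 0.48 with the length offset. Here 2 passed adjusted over the list alone, against 0 over all genes, with 31 without DKO non-tumour replicate 3, 1 without any 1 of the 6 tumour libraries, and 0 without Atg7KO non-tumour replicates 1 or 3 or DKO non-tumour replicates 1 or 2.

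Autophagy genes other than Atg7 were slightly higher in DKO non-tumour liver, with a median of 0.17 (camera adjusted p = 0.0241, and 0.761 with an estimated correlation), a call lost without Atg7KO non-tumour replicate 1 or DKO non-tumour replicate 1 (up to 0.0882). Gabarapl2, an ATG8 family member, stood at 31.6 ± 1.75 and 54.0 ± 6.19 CPM, Atg16l1, which directs ATG8 lipidation, at 27.1 ± 2.10 and 51.2 ± 9.29 CPM, and Atg5, its partner, at 47.9 ± 6.75 and 76.0 ± 15.2 CPM. These 3 passed adjusted over the list alone, against 0 over all genes, and 0 did without Atg7KO non-tumour replicates 1 or 3 or DKO non-tumour replicates 1 or 2. Female-biased genes fell by a median of 1.35 (camera adjusted p = 0.0347, and 0.944 with an estimated correlation), alongside the Xist and Y chromosome difference. In it the sulfotransferase Sult2a1, one of a family with shared sequence, stood at 175 ± 215 and 2.84 ± 4.34 CPM and the oxidase Hao2 at 22.5 ± 33.0 and 0.197 CPM. In it 4 passed adjusted over the list alone, against 0 over all genes, with 0 without Atg7KO non-tumour replicate 2 or DKO non-tumour replicates 1 or 3 and 2 without DKO non-tumour replicate 2. Without Atg7KO tumour replicates 2 or 3, 1 was higher. The list call was lost without Atg7KO non-tumour replicate 2 or DKO non-tumour replicates 1 or 3 (up to 0.177), and without the first of these the median was -0.57.

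Other lists shifted in the same comparison. Acute phase genes rose by 0.93 with 22 of 23 above 0 (camera adjusted p = 0.00896, and 0.944 with an estimated correlation), lost without Atg7KO non-tumour replicate 1 or DKO non-tumour replicate 2 (up to 0.378), with a median of 0.16 without the latter. The heme carrier Hpx stood at 5157 ± 2070 and 11440 ± 9550 CPM. NRF2 targets fell by 0.40 (0.0101, and 0.944), lost without Atg7KO or DKO non-tumour replicate 1 (up to 0.476), with a median of -0.12 without the former. Without DKO non-tumour replicate 3, 1 NRF2 target and 3 endothelial genes passed adjusted over the list alone. Endothelial markers fell by 0.39 (0.0145, and 0.944), lost without Atg7KO non-tumour replicate 2 (0.0674), and YAP targets by 0.44 (0.0241, and 0.944), lost without Atg7KO non-tumour replicates 1 or 3 or DKO non-tumour replicate 2 (up to 0.167) and with the length offset (0.153). Secreted plasma proteins rose by 0.35 (0.035, and 0.944), lost without Atg7KO non-tumour replicates 1 or 3 or DKO non-tumour replicates 1 or 2 (up to 0.476) and with the length offset (0.194). Their median was 0.12 without Atg7KO non-tumour replicate 1 and 0.07 with the offset. Fatty acid oxidation genes rose by 0.25 (0.0387, and 0.944), lost without Atg7KO non-tumour replicates 1 or 3 or DKO non-tumour replicate 1 (up to 0.926) and with the length offset (0.153). Their median was 0.74, 0.12 and 0.04 without Atg7KO non-tumour replicates 2, 1 and 3, turned to -0.05 without DKO non-tumour replicate 1, and was 0.10 with the offset. Single members passed adjusted over the list alone in 3 lists that camera did not call, against 0 over all genes. They were the p53 target Rps27l (92.5 ± 8.02 to 210 ± 52.9 CPM), the duct cell factor Sox9 (35.5 ± 14.2 to 13.1 ± 4.81 CPM) and Gldc (233 ± 39.4 to 97.3 ± 36.3 CPM). For Rps27l the log2 fold change was 1.18, or 0.52 with the length offset. Gldc was lost without any 1 of the 3 Atg7KO non-tumour libraries and DKO non-tumour replicates 1 and 2. The duct count of 1 was 0 without Atg7KO non-tumour replicates 1 or 3, Atg7KO tumour replicate 3, DKO non-tumour replicates 1 or 2 or DKO tumour replicate 3, and 2 without Atg7KO non-tumour replicate 2, Atg7KO tumour replicate 2 or DKO tumour replicates 1 or 2. Not called by camera were macrophage (adjusted p = 0.0888), P450 (0.109, and 0.0156 with the length offset), stellate (0.109), oncofetal (0.129), duct (0.157), T and NK cell (0.246, and 0.0156), erythroid (0.267), interferon (0.405, and 0.0286). The same held for inflammatory cytokine (0.42), male-biased (0.469), pericentral, S phase and ER stress (0.684 each), cholesterol (0.705), neutrophil (0.796), p53 (0.801), B and plasma cell (0.821), HMGB1 partner, bile acid and lipogenic (0.852 each) and periportal genes (0.887).

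In tumours Socs2 again rose in DKO, from 5.79 ± 1.28 to 29.7 ± 3.29 CPM, a log2 fold change of 2.36 with an SE of 0.24 and an edgeR adjusted p of 0.00161, with all 3 DKO libraries above all 3 Atg7KO libraries. Bglap3 (NM_001305449, mm10 chromosome 3, 88368616 to 88372741), of the osteocalcin family, fell from 11.4 ± 7.97 to 0.022 ± 0.0191 CPM (adjusted p = 0.0201). It was not called without DKO tumour replicate 1 (0.0706) or 2 (0.0769), and its paralogues can share reads. The other edgeR calls were Ddx3y (55.7 ± 12.5 CPM in DKO, adjusted p = 6.03e-06), Eif2s3y (41.7 ± 1.71 CPM, 6.03e-06), Kdm5d (14.4 ± 2.81 CPM, 8.17e-05) and Uty (13.9 ± 1.29 CPM, 0.00229), each at 0 to 0.0115 CPM in Atg7KO, and Xist, at 71.3 ± 29.6 CPM in Atg7KO and 0 in DKO (0.0108), which was not called without the low-count filter (0.0582). In total edgeR called 5 genes higher and 2 lower, 2400 genes (16.6%) had an unadjusted p under 0.05, DESeq2 called 269 higher and 282 lower, limma voom with quality weights called 14 higher and 23 lower, and 2931 genes (20.3%) did not overlap, against 10% by chance. On leaving out 1 library edgeR called 5 to 18 higher and 1 to 12 lower, with the most without DKO tumour replicate 3.

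Interferon response genes were lower in DKO tumours than in Atg7KO tumours. The membrane protein gene Bst2, which tethers viruses, stood at 275 ± 55.9 CPM in Atg7KO and 109 ± 20.6 CPM in DKO, a log2 fold change of -1.33 with an SE of 0.23 (edgeR adjusted p = 0.0708). The immunoproteasome subunits Psmb9 (57.0 ± 16.3 and 22.1 ± 6.25 CPM) and Psmb8 (168 ± 71.7 and 52.8 ± 24.7 CPM) stood apart in the same way, with no overlap between the libraries of the genotypes. The list fell by a median of 0.65, with 26 of 28 below 0 (camera adjusted p = 4.2e-07, and 0.745 with an estimated correlation). Of its members 7 passed adjusted over the list alone, against 0 over all genes, with 14 without Atg7KO tumour replicate 2, 4 without DKO tumour replicate 1, and 3 without Atg7KO tumour replicate 1 or DKO tumour replicate 2. Targets of p53 fell by 0.35 with 18 of 20 below 0 (camera adjusted p = 0.00216, and 0.745 with an estimated correlation), a call lost without Atg7KO tumour replicate 2 (0.0871). The stress cytokine Gdf15 stood at 24.0 ± 13 and 5.99 ± 1.69 CPM, Cdkn1a at 122 ± 35.0 and 47.9 ± 6.95 CPM, and the apoptosis gene Bbc3 at 16 ± 2.34 and 8.40 ± 1.75 CPM. Within the list 4 passed adjusted over the list alone, against 0 over all genes. The count was 0 without Atg7KO tumour replicate 2 or DKO tumour replicate 1, 1 without Atg7KO tumour replicate 1, and 2 without DKO non-tumour replicate 1 or DKO tumour replicate 2. NRF2 targets fell by 0.51 (camera adjusted p = 9.97e-05, and 0.745 with an estimated correlation), with Nqo1 at 397 ± 15.1 and 179 ± 76.4 CPM. In this list 0 passed adjusted over the list alone, but 3 did without Atg7KO non-tumour replicates 1 or 2 and 2 without DKO tumour replicate 3. T and NK cell markers fell by 0.64 (0.0446, and 0.979), a call lost without Atg7KO tumour replicates 1 or 3, DKO tumour replicate 1 or DKO non-tumour replicate 3 (up to 0.727) and with the length offset (0.157), with a median of -0.26 without Atg7KO tumour replicate 3.

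Cell cycle genes were lower in DKO tumours, with all 25 G2/M genes below 0 and a median of -0.76 (camera adjusted p = 9.68e-09, and 0.745 with an estimated correlation) and 21 of 25 S phase genes below 0 with a median of -0.42 (camera adjusted p = 0.000144, and 0.745 with an estimated correlation). Neither list had a member past 0.05 over all genes or adjusted over the list alone. Without Atg7KO non-tumour replicate 1 there were 10 G2/M genes, and without DKO tumour replicate 3 there were 2 G2/M and 6 S phase genes. YAP targets were higher, with 16 of 18 above 0 and a median of 0.78 (camera adjusted p = 4.13e-05, and 0.745 with an estimated correlation). Ankrd1, a classical YAP target, stood at 3.58 ± 1.64 and 46.0 ± 40.7 CPM, and Amotl2, which restrains YAP in turn, at 18.6 ± 2.02 and 62.2 ± 38.9 CPM. Of the list 4 passed adjusted over the list alone, against 0 over all genes, with 8, 7 and 10 without Atg7KO tumour replicate 2, DKO tumour replicate 2 and DKO tumour replicate 3, and 2 without Atg7KO tumour replicates 1 or 3 or DKO tumour replicate 1. Stellate markers were higher by 0.85 (camera adjusted p = 0.000385, and 0.931 with an estimated correlation), with Pdgfra at 6.17 ± 1.16 and 15.4 ± 3.22 CPM. Pdgfra was the 1 stellate gene to pass adjusted over the list alone, against 0 over all genes. The count was 6 without Atg7KO tumour replicate 2, 3 without DKO tumour replicate 1, and 0 without any 1 of Atg7KO tumour replicates 1 and 3, Atg7KO non-tumour replicate 3, DKO tumour replicates 2 and 3, and DKO non-tumour replicate 3. Duct markers were higher by 0.76 (camera adjusted p = 0.0158, and 0.931 with an estimated correlation), a call lost without Atg7KO tumour replicates 1 or 3 or DKO tumour replicate 3 (up to 0.13), with a median of 1.93 without Atg7KO tumour replicate 2. The keratin Krt7 stood at 1.16 ± 0.937 and 22.7 ± 26.8 CPM. Here 2 duct markers passed adjusted over the list alone, against 0 over all genes, with 13 without Atg7KO tumour replicate 2, 1 without DKO tumour replicate 3 and 0 without Atg7KO tumour replicates 1 or 3.

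Oxidative phosphorylation genes were lower in DKO tumours than in Atg7KO tumours, with 46 of 47 below 0 and a median of -0.50 (camera adjusted p = 2.93e-11, and 0.745 with an estimated correlation). The cytochrome oxidase subunit Cox5b stood at 255 ± 23.4 and 99.2 ± 12.0 CPM and the ATP synthase subunit Atp5o at 220 ± 16.9 and 107 ± 33.8 CPM. In it 2 passed adjusted over the list alone, against 0 over all genes. The count was 14 without DKO non-tumour replicate 3, 6 without Atg7KO tumour replicate 2, 0 without DKO tumour replicate 2, and 1 without any 1 of the 3 Atg7KO non-tumour libraries, Atg7KO tumour replicates 1 and 3, DKO non-tumour replicates 1 and 2, and DKO tumour replicate 1. Log2 fold changes followed gene length with a rho of 0.356 across genes, and with the length offset the score difference went from -0.48 to -0.18. Among periportal genes Aldh1b1, a mitochondrial aldehyde dehydrogenase, stood at 310 ± 66.8 and 69.9 ± 59.6 CPM, Cyp2f2 at 1255 ± 290 and 395 ± 212 CPM and the urea cycle enzyme Otc at 300 ± 71.8 and 130 ± 40.6 CPM. These 3 passed adjusted over the list alone, against 0 over all genes, in a list that camera did not call (adjusted p = 0.147). The periportal count was 0 without Atg7KO tumour replicate 2 or DKO tumour replicate 2 and 1 without Atg7KO tumour replicate 3. Oncofetal genes went both ways, with Afp at 34.1 ± 20.3 and 937 ± 1200 CPM and the imprinted RNA Rian at 41.0 ± 53.1 and 1.55 ± 2.17 CPM. Adjusted over the list alone 4 were higher and 3 lower, against 0 over all genes, and camera did not call the list (adjusted p = 0.873). The higher count was 2 without Atg7KO tumour replicate 1 or Atg7KO non-tumour replicate 3 and 0 without Atg7KO tumour replicate 3 or DKO tumour replicate 1, and the lower count was 0 without Atg7KO tumour replicate 1 or DKO tumour replicates 1 or 2. The other lists not called were pericentral (0.121), bile acid (0.231), autophagy (0.272), acute phase and lipogenic (0.394 each), erythroid and male-biased (0.448 each). The same held for P450 (0.473), macrophage (0.555), ER stress (0.83), HMGB1 partner, fatty acid oxidation and B and plasma cell (0.873 each), cholesterol (0.891), endothelial, secreted, female-biased and inflammatory cytokine (0.964 each) and neutrophil genes (0.967).

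The interaction asked whether the tumour effect differed between the genotypes, as the DKO effect minus the Atg7KO effect. Oxidative phosphorylation genes were lower in it, with 46 of 47 below 0 and a median of -0.97 (camera adjusted p = 4.78e-21, and 0.831 with an estimated correlation). Cox5b had a value of -1.61 with an SE of 0.34 and Cox7a2 of -1.28 with an SE of 0.29. Of its members 34 passed adjusted over the list alone, against 0 over all genes. The count was 11 without Atg7KO non-tumour replicate 3, 20 without DKO non-tumour replicate 1, 12 without DKO non-tumour replicate 2 and 15 without DKO tumour replicate 2. Gene length and the interaction followed each other with a rho of 0.574 across genes, and with the length offset 0 passed adjusted over the list alone and the score difference went from -0.91 with an SE of 0.26 to -0.20 with an SE of 0.18. YAP targets were higher, with all 18 above 0 and a median of 1.30 (camera adjusted p = 6.04e-06, and 0.831 with an estimated correlation), among them Ankrd1 at 3.83 with an SE of 0.98 and Amotl2 at 2.34 with an SE of 0.53. Within the list 6 passed adjusted over the list alone, against 0 over all genes, and 2 with the length offset. The count was 0 without Atg7KO tumour replicate 1, 2 without Atg7KO non-tumour replicate 3, and 1 without Atg7KO tumour replicate 3, DKO tumour replicate 1 or DKO non-tumour replicate 2.

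Stellate markers were higher in the interaction by a median of 1.44 (camera adjusted p = 0.000587, and 0.964 with an estimated correlation), with Pdgfra at 2.04 with an SE of 0.44, the elastic fibre gene Fbln2 at 3.02 with an SE of 0.84 and the collagen Col6a3 at 2.15 with an SE of 0.67. In this list 5 passed adjusted over the list alone, against 0 over all genes, with 9 without Atg7KO non-tumour replicate 2, 10 without Atg7KO tumour replicate 2 and 3 without Atg7KO non-tumour replicate 3 or DKO non-tumour replicate 1. It was 1 without Atg7KO non-tumour replicate 1, Atg7KO tumour replicate 3, DKO non-tumour replicate 2, or DKO tumour replicates 2 or 3, and 0 without Atg7KO tumour replicate 1. Duct markers were higher by 1.24 with 19 of 20 above 0 (camera adjusted p = 0.00123, and 0.964 with an estimated correlation). Interferon genes were lower by 0.46 (0.00455, and 0.964), a call lost without Atg7KO tumour replicate 1 (0.0605), and autophagy genes by 0.26 (0.0127, and 0.564). Without Atg7KO tumour replicate 2, 7 duct genes passed adjusted over the list alone, and 1 without DKO tumour replicate 2. Without DKO non-tumour replicate 3, 6 autophagy genes did, and 1 without Atg7KO tumour replicate 3 or DKO tumour replicate 3. Targets of p53 were lower by 0.41 (0.0224, and 0.835), a call lost without Atg7KO non-tumour replicate 2, Atg7KO tumour replicate 2, DKO non-tumour replicate 3 or DKO tumour replicate 3 (up to 0.111). S phase genes were lower by 0.29 (0.0416, and 0.964), a call lost without any 1 of Atg7KO non-tumour replicate 2, Atg7KO tumour replicate 2, DKO tumour replicates 1 and 2, and DKO non-tumour replicates 2 and 3 (up to 0.248). Without Atg7KO non-tumour replicate 2 the p53 median was -0.19 and the S phase median -0.11. Bst2 at -1.40 and the p53 target Rps27l at -1.17 each passed adjusted over the list alone, against 0 over all genes. The interferon count of 1 was 0 without any 1 of Atg7KO non-tumour replicates 2 and 3, Atg7KO tumour replicate 1, DKO non-tumour replicates 1 and 2, and DKO tumour replicates 1 and 2, and 2 to 4 without Atg7KO non-tumour replicate 1, Atg7KO tumour replicates 2 or 3, or DKO tumour replicate 3. The p53 count of 1 was 0 without any 1 of Atg7KO non-tumour replicates 2 and 3, Atg7KO tumour replicates 1 and 2, DKO non-tumour replicates 1 and 2, and DKO tumour replicates 1 and 3, and 2 without Atg7KO non-tumour replicate 1 or Atg7KO tumour replicate 3. Mki67 had a value of 1.17 with an SE of 0.36 (edgeR adjusted p = 0.179).

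No single gene passed the interaction test in edgeR, where the lowest adjusted p was 0.175. Unadjusted p was under 0.05 for 2582 genes (17.9%), or 1088 with the length offset, DESeq2 called 195 higher and 213 lower, and limma voom with quality weights called 0 and 0. The DESeq2 calls held long genes such as the scaffold Akap9 at 1.79 with an SE of 0.32, or 0.72 with the length offset, the DNA demethylase Tet3 at 2.05 with an SE of 0.39 and the adhesion gene Lpp, which overlaps the antisense gene Lppos, at 1.60 with an SE of 0.31. Lower in DESeq2 were the proton pump subunit Atp6v1g1 at -1.42 with an SE of 0.27, the complex I gene Ndufa11 at -1.81 with an SE of 0.35 and the heme synthesis gene Uros at -1.41 with an SE of 0.29. Lists not called were secreted plasma, endothelial and fatty acid oxidation (adjusted p = 0.159 each), female-biased and erythroid (0.166 each, and 0.0462 for female-biased with the length offset), periportal (0.181), male-biased and acute phase (0.293 each), NRF2 (0.376), oncofetal (0.383). The same held for bile acid, ER stress and lipogenic (0.473 each), pericentral (0.51), macrophage (0.555), T and NK cell (0.565), inflammatory cytokine (0.639), P450 (0.819), G2/M and neutrophil (0.912 each) and HMGB1 partner, B and plasma cell and cholesterol genes (0.925 each).

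Lists with no count of passing members given had 0 over all genes and 0 adjusted over the list alone with all 12 libraries. Among those that camera did not call, 46 of these counts per comparison and direction rose from 0 on leaving out 1 library, 42 of them to no more than 2. The other 4 reached 3 or more. Between DKO and Atg7KO tumours 5 pericentral genes were higher without DKO tumour replicate 1 and 3 without Atg7KO non-tumour replicate 2, and 3 female-biased genes without Atg7KO tumour replicate 3. In DKO tumours against non-tumour liver 3 stellate markers were higher without Atg7KO non-tumour replicate 1 and 2 without DKO tumour replicate 1. In DKO against Atg7KO non-tumour liver 3 oncofetal genes were lower without Atg7KO non-tumour replicate 2 and 1 without DKO tumour replicate 1.

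**Figure D4:**
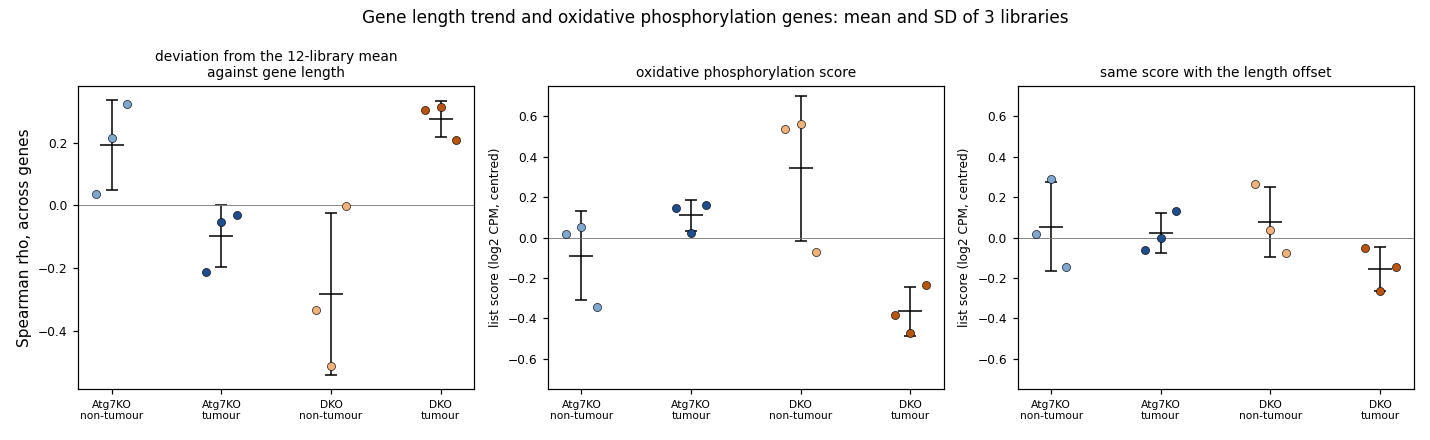
For each library, Spearman rho between gene length and a gene's deviation from its mean log2 CPM over all libraries, then the oxidative phosphorylation score, and the same score with the length offset. The rho ran from -0.51 in DKO non-tumour replicate 2 to 0.322 in Atg7KO non-tumour replicate 3, and the score contrast of the interaction from -0.91 without to -0.20 with the offset.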

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

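In this part the tests of gene length on the oxidative phosphorylation and pericentral lists, the tests of sex, the tests of the hepatocyte share and the counts over splits at an unadjusted p were chosen only after the result was seen. The test of the calls without DKO non-tumour replicate 3 and the counts of calls over other splits of the samples were chosen before. After first outcomes were seen, 2 criteria were changed. A first criterion for oxidative phosphorylation was whether its median lay outside the middle 95% of random lists matched on length and expression, which went against length as the whole cause with a share of 0.0054. It was replaced by separate criteria for the larger part and for the whole, because random draws of genes ignore the spread between libraries. The criterion for a lower hepatocyte share was changed to a difference within 0.3 of 0, under which the DKO tumours are undecided.

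The interaction of genotype and tissue asked whether tumours changed differently in DKO and Atg7KO livers, and camera with a preset correlation called 8 lists. Oxidative phosphorylation genes (adjusted p = 4.78e-21), interferon response genes (0.00455), autophagy genes (0.0127), p53 targets (0.0224) and S phase genes (0.0416) had the lower tumour effect in DKO. YAP targets (6.04e-06), stellate markers (0.000587) and duct markers (0.00123) had the higher tumour effect in DKO. None of the 8 was called with an estimated correlation, where the lowest adjusted p was 0.564, or by fry. In single genes edgeR called 0, with 2582 at an unadjusted p under 0.05, against 195 higher and 213 lower in DESeq2. Since the real split of the samples gave 0 genes, all 100 of 100 splits drawn gave at least as many and that count decides nothing about chance. Of the other splits the highest gave 19 genes, which can come from a structure of the samples that was not tested. By the count at an unadjusted p under 0.05, a measure chosen only after the result was seen, 1 of 100 splits was as large, the real one with 2582 genes, and the highest other had 2347.

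The first pattern weighed is that differences follow gene length, with a rho of 0.574 in the interaction and 0.495 between DKO tumours and non-tumour liver. Against length as a small part only, 10000 random lists matched on length and expression had a median of -0.791 in the interaction, against -0.97 for the oxidative phosphorylation list and -0.219 for lists matched on expression alone, which is consistent with length accounting for the larger part of the shift. The 597 calls between DKO tumours and non-tumour liver without DKO non-tumour replicate 3 became 0 with the length offset, as their median absolute change went from 1.23 to 0.658 while the median SE stayed near 0.25 (0.254 and 0.24). Whether length makes the whole shift cannot be told apart from a part due to genotype or tumour, since the corrected contrast was -0.20 with an SE of 0.18 in 12 libraries, while the matched lists gave the share of 0.0054. What produces the length trend (RNA quality, library preparation or a change in the tissue) was not tested and stays open.

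The second pattern is the set of genes called between the genotypes. Every DKO library held at least 1898 reads of the 4 Y genes and every Atg7KO library at most 2, so for the sex chromosome genes sex is enough to make the calls. For Socs2, Coq10b, Mthfsl and Bglap3 the loss of Hmgb1 and sex cannot be told apart, because 0 libraries had sex chromosome reads that differed from the rest of their genotype. Growth hormone signalling, on which Socs2 feeds back, differs between the sexes of mice. A share of splits under 0.05 cannot be reached with 10 splits of the 6 libraries fitted alone: the real split gave 9 genes and the highest other 1 in non-tumour liver, and 8 and 0 in tumours, or 2430 and 2101, and 1687 and 868, at an unadjusted p under 0.05.

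The third pattern is the fall of pericentral genes in the tumours of both genotypes. A length trend is argued against, since with the length offset the medians were -2.16 in Atg7KO and -1.33 in DKO, below -1 in both. A lower share of hepatocytes is argued against in Atg7KO, where the pericentral minus periportal score was lower by more than the sum of both SDs (difference -1.98, sum 1.03). In DKO that difference was -1.23 with a sum of SDs of 1.4, so a lower hepatocyte share and a loss of pericentral identity cannot be told apart there. Where in the liver lobe each piece was taken and a clonal origin of tumours outside the pericentral zone stay open as untested; a share under 0.05 cannot be reached with 10 splits of the 6 libraries fitted alone, where the real and the highest other split gave 0 and 0 calls in Atg7KO, which decides nothing, and 1 and 0 in DKO, and 2258 and 902 genes at an unadjusted p under 0.05 in Atg7KO and 2758 and 952 in DKO.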

How the results depend on the processing

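The alternatives marked above as added were chosen only after the result was seen. The other alternatives were planned. Depth limits genes of few reads, and 3 libraries per group limit single genes: most simulated changes of 2-fold were missed. The cause was not tested for any change below except where it is named.

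DESeq2 called 261 genes higher and 350 lower between Atg7KO tumours and non-tumour liver, 600 and 502 in DKO, 87 and 102 between the genotypes in non-tumour liver, 269 and 282 in tumours, and 195 and 213 in the interaction, against 0 and 0, 0 and 0, 7 and 1, 5 and 2, and 0 and 0 in edgeR. Voom with quality weights called 105 and 227, 0 and 0, 338 and 223, 14 and 23, and 0 and 0 in the same order. Without legacy deviances edgeR called 1 gene higher in Atg7KO tumours, 2 lower in DKO non-tumour liver, and 9 higher and 15 lower in DKO tumours than in Atg7KO tumours. With the replicate block 3 genes were lower in Atg7KO tumours, 3 lower in DKO non-tumour liver, 1 lower in DKO tumours (Bglap3 then had an adjusted p of 0.0701, and Mthfsl in non-tumour liver 0.0808) and 1 higher in the interaction. Tumour and non-tumour libraries of the same number had deviations that correlated across genes at 0.016, 0.056 and 0.311 in Atg7KO and 0.0744, 0.332 and 0.0242 in DKO. Of these 6 pairs 2 were the best match by that measure, while by the plain correlation of libraries the pair of DKO replicates 3 was the highest of all pairs, at 0.9858. Fitting only the 2 groups compared gave 1 gene higher in DKO tumours than non-tumour liver and 3 lower in DKO non-tumour liver. In DKO tumours against Atg7KO tumours 5 genes were lower with RLE factors, with robust estimation off and without a filter. With no filter 0 genes were lower in DKO non-tumour liver. With the length offset the correlation of the tumour effects between genotypes was 0.4344 instead of 0.3263.

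Leaving out 1 library at a time gave 0 to 1 genes higher (1 without Atg7KO tumour replicate 3) and 0 to 3 lower (3 without Atg7KO non-tumour replicate 2, 1 without DKO non-tumour replicate 1) in Atg7KO tumours. In DKO tumours it gave 0 to 297 higher and 0 to 300 lower, each highest without DKO non-tumour replicate 3, and with the length offset added 0 and 0. In DKO non-tumour liver it gave 5 to 8 higher and 0 to 2 lower, with 0 without any of its 3 libraries and 2 without DKO tumour replicate 2. Between the tumours it gave 5 to 18 higher and 1 to 12 lower, both highest without DKO tumour replicate 3. The interaction gave 0 and 0. The correlation of tumour effects ran from 0.2323 without Atg7KO non-tumour replicate 2 to 0.3699 without Atg7KO non-tumour replicate 1.

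Of the 63 list calls, 63 were lost with an estimated correlation and 62 with fry, and 63 stayed with RLE factors and with the replicate block. With the length offset 57 stayed and 5 were lost, and oxidative phosphorylation in Atg7KO tumours reversed (adjusted p = 0.638), as the offset removes a trend that raised short genes there. Another 7 lists were called only with the length offset. On leaving out 1 library the median of 24 of the 63 moved over 2-fold, of which 3 turned. Of 296 gene results, DESeq2, whose calls helped choose them, brought 119 past the threshold and took 0 below it. The 1 CPM filter changed the call of 0 of 294. With few edgeR calls neither 0 shows stability.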

Other observations

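No test was run on the values in this part, and the genes were chosen only after their values were seen. Igf2, the fetal growth factor, ranged from 10.5 to 3370 CPM in the 3 Atg7KO tumours and from 39.3 to 2850 CPM in the 3 DKO tumours, against 7.5 to 116 CPM in Atg7KO and 3.01 to 7.42 CPM in DKO non-tumour liver. H19, the RNA transcribed beside Igf2, ranged from 80.4 to 10200 CPM in Atg7KO tumours and from 29.9 to 489 CPM in DKO tumours, against 113 to 813 CPM in Atg7KO and 2 to 43 CPM in DKO non-tumour liver. Gpc3, a fetal proteoglycan used to stain liver cancer, stood at 20.5 ± 20.8, 9.94 ± 7.32, 17.8 ± 1.97 and 264 ± 417 CPM in Atg7KO non-tumour liver, Atg7KO tumours, DKO non-tumour liver and DKO tumours, with 745 CPM in DKO tumour replicate 1.

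DKO tumour replicate 1 stood apart from the other libraries, with the lowest quality weight, 0.271, among the 12 libraries and a position of 67.13 on the first and 86.22 on the second principal component. It also had the lowest pericentral score, -2.54, the highest YAP score, 1.39, and the highest Afp, 2320 CPM. Atg7KO non-tumour replicate 2 had the highest pericentral score, 1.82, and the most Xist reads, 12216. No label sets either library apart, and no explanation was tested for them.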
